A study of Rattus norvegicus with 4 samples.

How the data were processed

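Total RNA from rat myometrium was measured on 4 Affymetrix arrays of the RG_U34A type, 1 for each of control and estradiol benzoate at 6 h and at 24 h. Per the labels, each array carried biotin-labelled RNA pooled from 6 animals. The values used are the probe set intensities the authors deposited in 1 table of the series. Per the submitters' processing notes they were made with MAS5, the Affymetrix method that subtracts mismatch signal and scales each array. The version and settings are not given in the sources used here. The 2% trimmed mean of each column was 500, so the deposited intensities had been scaled to that target. The deposited experiment records of the instruments, which hold other values such as wash steps, were read for scan day, chip lot and fluidics. Per the file headers the arrays were of the same lot, the arrays at 24 h were scanned on 1 day and those at 6 h on another, and the wash record of the control array at 24 h stopped with a communication error.

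The table holds 8799 probe sets, of which 59 were Affymetrix controls and were left out of comparisons. A platform table gave exactly 1 gene symbol for 7018 probe sets, several for 308 and none for 1473, and only the first were named. Symbols were looked up by gene identifier among the RefSeq genes of the rat, which updated 0 of them, and 24 probe sets kept the symbol of the array. The signals were scaled to a common trimmed mean, raised to a floor at each array's 40th percentile and turned to log2. The floors lay between 89.5 and 108 signal units. A probe set counted as different when the log2 difference reached 1, that is 2-fold, and the brighter array was above its floor. With the dimmer array at the floor, the fold is a bound, written as at least N-fold. With both arrays at the floor no fold is given for a gene. In medians over lists or probe sets such genes enter as the log2 ratio of the 2 floors. A median can therefore equal that ratio, -0.17 at 24 h and -0.08 at 6 h, and is then set by the floors. A gene was represented by its brightest probe set, which gave 4736 genes, and 3622 were measured, that is above the floor on at least 1 array. Probe sets of 1 gene passed the 2-fold rule in both directions for 2 genes at 6 h and 11 at 24 h. The number of arrays limits the precision: with 1 array per group there is no spread between replicates, and animals cannot be told from each other within a pool.

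The comparisons, the 33 gene lists and the rule for naming genes were fixed before the data were examined. For each list the median log2 difference over its measured genes was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5. Chance would give 1.65 such lists per comparison if the genes of a list varied independently. At 24 h 6 lists stood apart on the higher side and 5 on the lower. At 6 h these counts were 1 and 10, and between the 2 controls 4 and 8. The percentile describes these arrays and is no p-value. Named genes were, per estradiol comparison, the 12 largest differences in each direction measured on both arrays that also held 2-fold against the other control, up to 4 bounds per direction, up to 4 genes per list, and 11 genes fixed by name. To these came up to 6 genes past the rule at both times in each pattern, the 5 largest per direction between the controls, and 5 per direction from the fit of both times. Not all that the rule allows are named. That fit used limma's lmFit and eBayes on the floored log2 values with treatment and time as terms, 1 residual degree of freedom, and a threshold of 0.05 after Benjamini-Hochberg adjustment.

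Each step was tested on simulated arrays built from the real mean signals with noise of SD 0.3 on the log2 scale and 200 changed probe sets. The 2-fold rule recovered 92% of 3-fold and 100% of 8-fold changes in the simulated 6 h comparison over 8740 probe sets, and 89% and 100% at 24 h. It called 1.69% and 1.56% of unchanged probe sets. The list percentile set apart 6% of 200 unchanged lists and 100% of 50 lists shifted by 0.5, over 3369 genes. The simulated limma fit of both times, over 5635 probe sets, called 90% of 3-fold and 100% of 8-fold changes and 0% of unchanged ones. Simulated noise was drawn per array, changes were the same at both times, and lists were random genes. Log2 differences between pairs of real arrays had SDs from 0.66 to 0.82. These rates describe the simulated settings and are not error rates of the real comparisons.

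The alternatives were values as deposited, scaling to a common median, quantile normalization, floors at the 20th and 60th percentiles, a pseudocount in place of the floor, 1.5-fold and 3-fold rules, the mean of both controls, the mean of a gene's probe sets, and leaving out probe sets with names ending in _x_at or _s_at. For the counts at 6 h and 24 h they also included a 2-fold difference against each of the 2 controls. For limma they also included no filter on dim probe sets and a trend of the variance with intensity. Values as deposited were identical to the scaled ones and test nothing. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.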

Results

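Gene expression was measured in the myometrium, the smooth muscle wall of the uterus, of rats aged 60 days without ovaries. The animals had received estradiol benzoate, an ester that releases estradiol slowly, at 10 µg per kg of body weight, or its vehicle, and the uterus was taken after 6 or 24 h. Treatment and time made 4 groups, and each was measured on 1 oligonucleotide array carrying RNA pooled from 6 animals. No group has replicate error, so a difference within a time compares 2 pools and was not tested. The only test is a limma fit of both times together. Median signals lay between 143 and 169 at a common trimmed mean of 500, and 6157 of 8740 probe sets were above the signal floor on at least 1 array. The 3′ over 5′ signal ratio, a sign of RNA integrity, lay between 1.05 and 1.15 for Gapdh and between 1.23 and 1.39 for Actb. Both arrays at 24 h were scanned on 1 day and both arrays at 6 h on another, so each estradiol comparison lies within a scan day. Time and scan day cannot be told apart. Spiked-in control transcripts were 2.32-fold brighter at 24 h than at 6 h by geometric mean over 9 probe sets, and 1.35-fold brighter with estradiol than in the control at 24 h. At 6 h they were 1.31-fold brighter on the array labelled control.

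Igf1, Pgr, S100g and Hsd11b2, which estrogen is known to induce in the rat uterus, stood high on the estradiol array at 24 h and low on the array labelled estradiol at 6 h. Igf1, a growth factor, had a signal of 5182 with estradiol and 665 in the control at 24 h, but 704 on the array labelled estradiol and 7872 on the array labelled control at 6 h. Pgr, the progesterone receptor, read 2143 against 654 at 24 h, and 461 against 2669 in the same order at 6 h. S100g, the calcium-binding protein calbindin-D9k, read 12673 against 4619 at 24 h and 1306 against 13858 at 6 h. Hsd11b2, the enzyme that inactivates glucocorticoids, read 6123 against 809 at 24 h and 462 against 3849 at 6 h. These 4 genes go against the labels at 6 h, so directions at 6 h are given for the arrays as labelled. Over all probe sets above the floor, the log2 differences between the array labelled estradiol at 6 h and the control at 24 h had an SD of 0.66, the smallest of the 6 array pairs. The SD was 0.70 between the 2 arrays at 6 h, 0.79 between those at 24 h and 0.82 between the 2 controls. It was 0.73 between the array labelled control at 6 h and the estradiol array at 24 h, and 0.76 between the 2 arrays labelled estradiol.

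**Figure D1:**
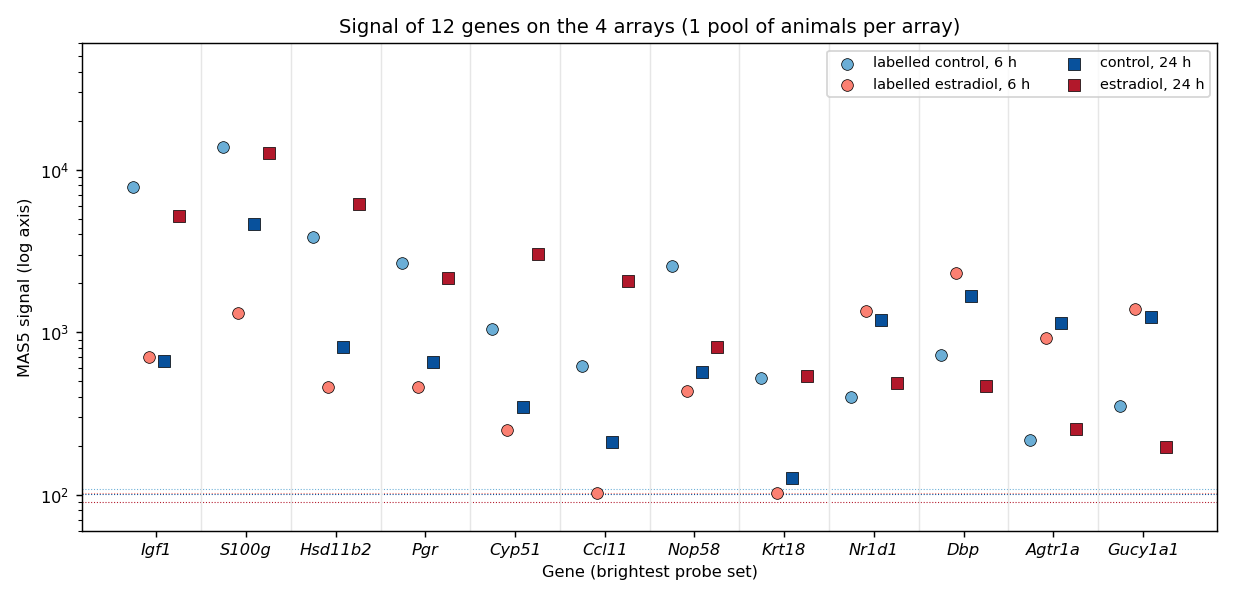
MAS5 signal on a log axis for 12 genes on each of the 4 arrays, with circles for 6 h and squares for 24 h; dotted lines mark the floor of each array, and a value under its floor is drawn at the floor. Igf1 stands at 7872 and 5182 on the array labelled control at 6 h and the estradiol array at 24 h, and at 704 and 665 on the other 2 arrays.

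The comparison at 24 h asks what the myometrium expressed 24 h after estradiol. Keratins of the epithelium were higher in the same pool, and epithelium carried along is not excluded. Which cells a difference came from was not measured. The lists of cholesterol synthesis, endoplasmic reticulum folding and uterine estrogen response stood apart on the higher side, with 9 of 16, 6 of 20 and 10 of 27 genes at least 2-fold higher with estradiol. The clock list stood apart on the lower side, with 4 of 9 genes lower, though not against the mean of both controls. That mean holds the 6 h control, whose label Igf1, Pgr, S100g and Hsd11b2 go against. Here and below, it therefore cannot decide on differences at 24 h. Among genes not above the floor in either control, Kap, an androgen-regulated kidney protein, was at least 18.2-fold higher with estradiol, Cuzd1 at least 13.0-fold and complement C3 at least 11.1-fold. Ccl11, the eosinophil attractant eotaxin, was 9.82-fold higher, Mmp7, a matrix-degrading protease, 6.92-fold and Spon1 6.46-fold. Efemp1, a matrix glycoprotein, was 9.04-fold lower, Cxcl13, a B cell attractant, 5.24-fold, Marcks 4.49-fold, Cpe, a peptide-processing enzyme, 4.19-fold and Csnk1d, a casein kinase, 4.14-fold. In all, 511 probe sets were at least 2-fold higher and 515 at least 2-fold lower, 16.7% of those above the floor, which made 310 and 290 genes. The median over probe sets was -0.17 on the log2 scale, which is the log2 ratio of the 2 floors, the value of probe sets at both. With arrays scaled to a common median the split was 634 higher against 363 lower. Without the 186 probe sets that were at least 2-fold lower on the 24 h control than on each of the other 3 arrays, a setting chosen after the data were seen, 325 were higher, which follows by construction because each of the 186 counts as higher. Those 186 include probe sets of Acat2, Col15a1, Copz1, Dkc1, Erp29, Igfbp5, Irf7, Lyz2, Mxi1, Odc1, Psmd11, Taf10 and Zfp36.

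Cholesterol synthesis was the gene list with the highest median at 24 h, a log2 difference of 1.66 at percentile 100 of random lists. Of its 16 measured genes 9 were at least 2-fold higher and 0 lower. Idi1 was at least 9.79-fold higher, Cyp51, the lanosterol demethylase, 8.73-fold, Fdft1, the squalene synthase, at least 6.01-fold and Sqle, which oxidises squalene, 5.11-fold. Mvd was at least 4.47-fold and Insig1, a brake on this pathway, 3.79-fold higher. Acat2 was 11.0-fold higher, but its signal on the 24 h control was also 3.66-fold lower than on the 6 h control. The list of uterine estrogen response genes had a median of 0.55, with 10 of 27 genes higher and 1 lower. Among these, Igf1 was 7.79-fold, Hsd11b2 7.57-fold, Odc1, the first enzyme of polyamine synthesis, 6.97-fold, Pgr 3.27-fold and S100g 2.74-fold higher. Oxtr, the oxytocin receptor, was higher by a log2 difference of at least 1.58, and Gja1, which forms the gap junctions of labour, was 2.13-fold higher. Esr1, the estrogen receptor, was 1.31-fold lower and Vegfa 1.60-fold lower, both under the 2-fold rule, as were Fos at 1.54-fold lower and Myc at 1.09-fold lower. Cd24, a surface glycoprotein, was 6.35-fold higher. Against the mean of both controls Pgr and S100g were under 2-fold, as Pgr was with the mean of its probe sets. Over all comparisons, 28 values of named genes lost the 2-fold call with the mean of a gene's probe sets. Against the 6 h control alone, chosen after the data were seen, the list's median lay inside the random range. Settings with the 6 h control rest on a label that Pgr and S100g go against, so they cannot decide on these 24 h differences.

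Endoplasmic reticulum folding genes had a median of 0.79 at 24 h, also at percentile 100, with 6 of 20 higher and 1 lower. The co-chaperone Dnajb9 was at least 4.56-fold, Erp29 2.98-fold and Pdia6, a disulfide isomerase, 2.47-fold higher, while Ddit3, a stress-induced transcription factor, was 2.77-fold lower. Proteasome genes had a median of 0.40 at percentile 99.8, with 4 of 24 higher, namely Psmd11 at 11.4-fold, Psmd2 at 3.23-fold, Psmc3 at 2.60-fold and Psmc5 at 2.51-fold. Ribosome biogenesis genes had a median of 0.50, and 3 of 10 were higher, Dkc1 by at least 8.45-fold, Mybbp1a by 3.55-fold and Ddx21 by 2.19-fold. Psmd11 and Dkc1 belong to 38 probe sets at least 4-fold lower on the 24 h control than on each of the other 3 arrays, which lay within 2-fold of each other. Against the mean of both controls the ribosome biogenesis median was -0.24, and Mybbp1a, Ddx21, Erp29, Psmc3 and Psmc5 were under 2-fold. Against the 6 h control alone, chosen after the data were seen, the proteasome median lay inside the random range.

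Extracellular matrix genes had a median of 0.21 at 24 h, at percentile 99.2, with 4 of 32 higher and 3 lower. Col15a1, a collagen, was 8.46-fold higher, the proteoglycan Vcan 3.87-fold and Loxl1, a collagen and elastin crosslinking enzyme, 3.73-fold, while Postn was 4.92-fold lower. Col15a1 was 4.22-fold lower on the 24 h control than on the 6 h control. Matrix proteases and their inhibitors had a median of -0.54, at percentile 0.51, with 2 of 20 higher and 4 lower. Mmp11 was 4.66-fold and Serpine2, a protease inhibitor, at least 4.53-fold lower, against the 6.92-fold higher Mmp7. Clock genes had a median of -0.87, with Per2 5.30-fold, Nr1d2 4.24-fold, Dbp 3.60-fold and Nr1d1 2.43-fold lower, which were all 4 of 9 genes past the rule.

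Markers of other cell types also differed at 24 h. Macrophage and leukocyte markers had a median of -0.65, with 6 of 20 lower and 3 higher. RT1-Da, a class II antigen-presentation gene, was 3.44-fold and Cd53 2.57-fold lower, while lysozyme Lyz2 was 3.25-fold and Coro1a at least 2.53-fold higher. Endothelial markers had a median of -0.73 with 1 of 7 lower, the growth factor receptor Flt1 at 2.01-fold, which was under 2-fold with arrays scaled to a common median or quantile normalized. Endometrial stroma markers had a median of -0.66 with 2 of 9 lower, Mme by at least 3.66-fold and Vcam1, an adhesion molecule, by at least 2.52-fold. Against the mean of both controls the endothelial, stroma, matrix protease and clock lists did not stand apart from random lists. With the mean of a gene's probe sets the stroma and macrophage lists did not, nor the stroma list with quantile normalization or either other floor. Of 11 epithelial markers 5 were higher and 1 lower, with a median of 0.25 inside the random range. The keratins Krt8, Krt18 and Krt19 were 4.84-fold, 4.25-fold and 4.32-fold higher and the adhesion molecule Epcam 2.79-fold.

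Contraction, channel and cell cycle lists did not stand apart at 24 h. Of 21 smooth muscle cytoskeleton genes 1 was 2-fold lower, Cnn3, at 2.21-fold, which was under 2-fold when arrays were scaled to a common median. Acta2, the smooth muscle actin, was 1.03-fold and Actg2 1.65-fold higher. Contraction-associated genes numbered 4 higher and 4 lower of 36. The angiotensin receptor Agtr2 was at least 3.88-fold higher and its relative Agtr1a 4.45-fold lower, Gucy1a1, a subunit of the nitric oxide receptor, 6.37-fold lower and Pln, which restrains the calcium pump of the sarcoplasmic reticulum, 3.16-fold lower. Of 30 potassium channel genes 2 were higher, Kcns3 at 2.71-fold and Kcnf1 at least 2.63-fold, and 3 lower, among them Kcnma1, the large-conductance calcium-activated channel, at least 2.36-fold. Of 12 calcium channel genes Cacna1b and Cacna1d were at least 4.32-fold and 4.29-fold lower. Of 24 cell cycle genes Ccnb1, a mitotic cyclin, was at least 2.12-fold and Top2a, a topoisomerase, 2.09-fold higher. With a floor at the 60th percentile the 24 h differences of Gja1, Ccnb1 and Top2a became -0.12, -0.13 and -0.03. The -0.13 of Ccnb1 is the log2 ratio of the raised floors, so its change of sign is set by the floors. Oxtr, Agtr2, Pln, Kcnma1, Cacna1b, Cacna1d and Epcam were then under 2-fold.

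The other lists did not stand apart at 24 h. Their median log2 differences were -0.17 for contraction-associated genes, -0.11 for the smooth muscle cytoskeleton, -0.32 for potassium channels, -0.49 for calcium channels and 0.03 for the cell cycle. They were -0.13 for immediate-early genes, -0.24 for heat shock and oxidative stress, 0.16 for translation factors and tRNA synthetases, 0.07 for cytosolic ribosomal proteins and 0.13 for oxidative phosphorylation. They were 0.10 for glycolysis, -0.40 for growth factors, -0.51 for the Wnt and Notch pathways, -0.19 for cytokines and 0.00 for the interferon response. Among cell type markers they were -0.30 for granulocytes and mast cells, -0.17 for lymphocytes, -0.17 for adipocytes and -0.52 for blood cells. They were -0.29 for nerve and -0.15 for skeletal muscle and mesothelium. The -0.17 of contraction-associated genes, lymphocytes and adipocytes is the log2 ratio of the 2 floors and no measured difference.

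The comparison at 6 h asks for the early response. On the array labelled estradiol, the lists of ribosome biogenesis, immediate-early genes, cytokines, cholesterol synthesis and uterine estrogen response stood apart on the lower side, with 7 of 10, 10 of 22, 10 of 31, 6 of 16 and 10 of 27 genes at least 2-fold lower than on the array labelled control. The clock list stood apart on the higher side, with 4 of 9 genes higher. Galr2, a galanin receptor, was at least 13.4-fold higher with the estradiol label, Igfbp5, which binds insulin-like growth factors, 6.05-fold, Pnrc1 5.16-fold, Gstk1 4.97-fold and Tcp11l2 4.47-fold. Ddr2, a collagen receptor, was 4.24-fold, Igfbp3 4.01-fold, Pygb, which breaks down glycogen, 3.98-fold, Itpr1, a calcium release channel, 3.74-fold and Nr2f2 3.21-fold higher. Igf1 was 11.2-fold, S100g 10.6-fold, Hsd11b2 8.33-fold, Cd24 7.33-fold, Ccl2, a monocyte attractant, 6.97-fold and Pgr 5.79-fold lower. The galactosyltransferase gene B4galt1 was at least 6.51-fold and Ackr3, a chemokine receptor, at least 4.64-fold lower. The counts were 427 probe sets higher and 331 lower with the estradiol label, 12.3% of those above the floor, or 232 and 182 genes. These directions follow labels that Igf1, Pgr, S100g and Hsd11b2 go against. Against the 24 h control in place of the 6 h control, a setting chosen after the data were seen, 170 probe sets were lower.

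Ribosome biogenesis had the lowest list median at 6 h, -1.58 at percentile 0 of random lists, with 7 of 10 genes lower and 0 higher. Nop58, of the nucleolar complexes that modify ribosomal RNA, was 5.91-fold, Mybbp1a 3.84-fold, Gnl3 3.76-fold and Nolc1 3.39-fold lower. Translation factors and tRNA synthetases had a median of -0.41 with 3 of 28 lower and 1 higher, and Tars1 was 2.90-fold and Eif2s1, an initiation factor, 2.37-fold lower. Immediate-early genes had a median of -0.79, with 10 of 22 lower and 0 higher. Atf3 was 3.71-fold, Klf4 2.98-fold, Myc 2.94-fold, Nr4a3 2.44-fold, Dusp1, a kinase phosphatase, 2.37-fold and Fos 2.25-fold lower. Cytokine, chemokine and acute phase genes had a median of -0.62, with 10 of 31 lower and 2 higher. Besides Ccl2, Ccl11 was at least 6.03-fold, Il4r 4.67-fold and Stat3, a cytokine-activated transcription factor, 3.71-fold lower, while Il33, an alarm cytokine, was 4.49-fold higher.

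Cholesterol synthesis had a median of -0.70 at 6 h, with 6 of 16 lower and 0 higher, and uterine estrogen response genes one of -0.58, with 10 of 27 lower and 2 higher. Cyp51 was 4.21-fold, Idi1 at least 3.67-fold, Insig1 3.01-fold and Mvd 2.84-fold lower with the estradiol label. Endoplasmic reticulum folding genes had a median of -0.37, at percentile 0.51, with Hspa5, the chaperone BiP, 3.07-fold lower and Dnajb9 2.53-fold higher. Proteasome genes had a median of -0.36, with 1 of 24 lower, Psmc5 at 2.33-fold. Clock genes had a median of 0.72, with 4 of 9 higher and 1 lower. Nr1d1 was 3.38-fold, Dbp 3.21-fold and Per2 2.15-fold higher and Bhlhe40 2.21-fold lower. Against the 24 h control, chosen after the data were seen, some lists no longer stood apart. Their medians were 0.02 for uterine estrogen response, which is the log2 ratio of the 2 floors, -0.11 for ribosome biogenesis and 0.03 for translation factors. They were -0.09 for cholesterol synthesis, -0.20 for immediate-early genes, -0.05 for cytokines, -0.17 for macrophage markers and -0.06 for the clock. Endoplasmic reticulum folding at -0.37, the proteasome at -0.28 and blood cell markers at -0.82 still stood apart on the lower side. Against the mean of both controls the endoplasmic reticulum list did not stand apart, and Fos, Mybbp1a, Nolc1, Idi1, Mvd, Nr1d1, Per2 and Tars1 were under 2-fold.

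Among other cell types at 6 h, blood cell markers had a median of -0.64 with Hba-a3, a hemoglobin chain, 2.01-fold lower, which was under 2-fold with arrays scaled to a common median. Macrophage markers had a median of -0.30, at percentile 1.02, with 2 of 20 lower, the antibody receptor Fcgr2b at 2.55-fold and Coro1a at least 2.04-fold. Of 11 epithelial markers 4 were lower and 0 higher, with a median of -0.36 inside the random range. Krt18 was at least 5.07-fold, Krt8 at least 3.94-fold and Krt19 2.39-fold lower. Of 36 contraction-associated genes 5 were higher and 2 lower. Agtr1a was 4.23-fold, Gucy1a1 3.92-fold and Pln 3.47-fold higher, and Oxtr at least 2.04-fold lower. Of 30 potassium channel genes Kcnd3 at 3.03-fold and Kcnh2 at 2.60-fold were higher and 3 were lower, among them Kcna1, at least 4.01-fold, and Kcnf1, at 3.35-fold. With a floor at the 60th percentile Oxtr and Coro1a were at the floor on both arrays. The 0.04 they share there is the log2 ratio of the raised floors and no measured difference. The macrophage list then did not stand apart, and Krt8, Krt18, Krt19, Pln, Kcna1 and Kcnf1 were under 2-fold. Acta2 was 1.27-fold and Vegfa 1.64-fold lower, and Esr1 was at the floor on both arrays.

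The other lists did not stand apart at 6 h. Their median log2 differences were -0.08 for contraction-associated genes, -0.32 for the smooth muscle cytoskeleton, -0.16 for potassium channels, 0.08 for calcium channels and -0.06 for the cell cycle. They were -0.12 for heat shock and oxidative stress, -0.15 for cytosolic ribosomal proteins, 0.09 for oxidative phosphorylation, -0.18 for glycolysis and 0.04 for extracellular matrix. They were 0.21 for matrix proteases, -0.08 for growth factors, 0.22 for the Wnt and Notch pathways and -0.07 for the interferon response. Among cell type markers they were 0.06 for endometrial stroma, -0.08 for endothelium, -0.10 for granulocytes and mast cells and -0.09 for lymphocytes. They were -0.30 for adipocytes, -0.17 for nerve and -0.11 for skeletal muscle and mesothelium. The -0.08 of contraction-associated genes, growth factors and endothelium is the log2 ratio of the 2 floors and no measured difference.

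**Figure D2:**
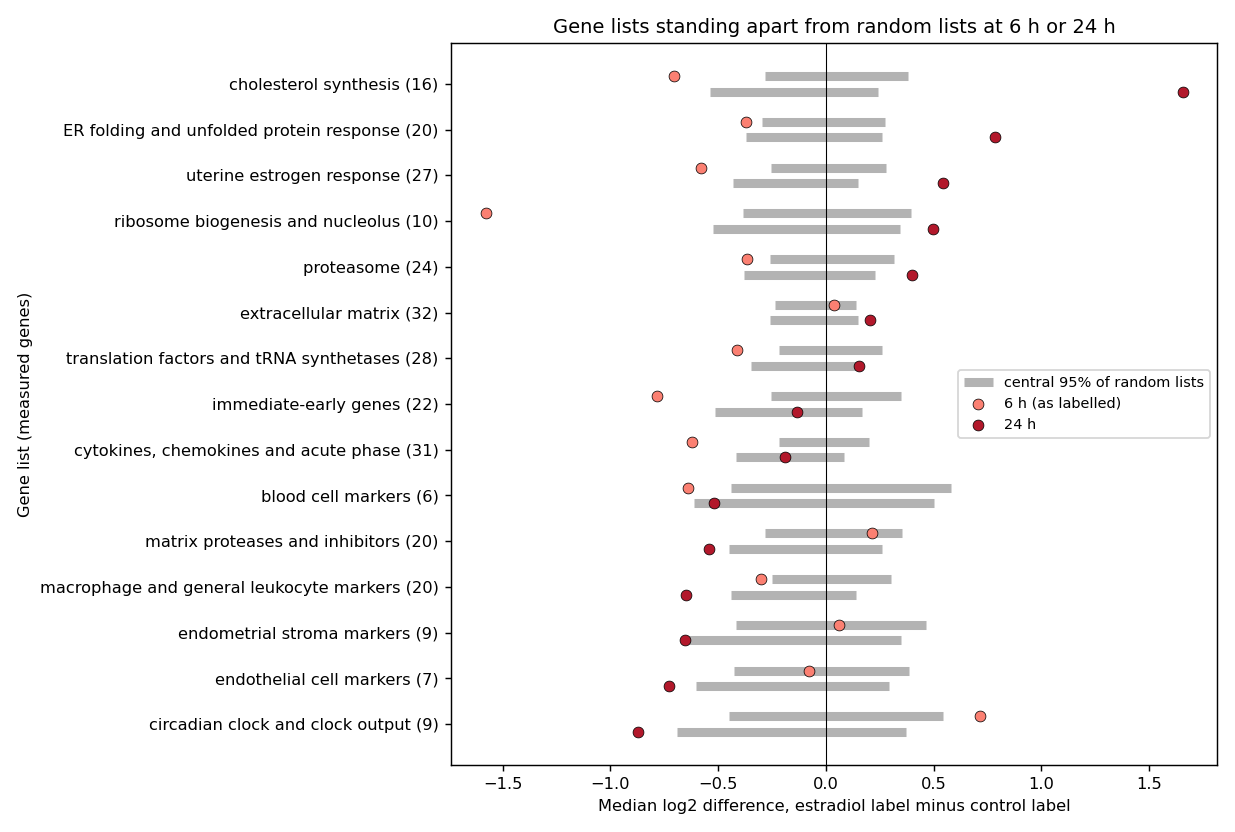
Median log2 difference, array with the estradiol label minus array with the control label, for the 15 gene lists that stood apart from random lists at 6 or 24 h, with measured genes in brackets; each gray bar spans the central 95% of random lists of the same size and signal. Cholesterol synthesis lies at -0.70 at 6 h and 1.66 at 24 h, and the clock list at 0.72 and -0.87.

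The crossing of treatment with time asks whether the differences at 24 h resembled those at 6 h. Genes past the 2-fold rule at both times ran mostly in opposite directions as labelled. Of them 69 were higher at 6 h and lower at 24 h, where independent lists would share 18.6, and 52 were lower at 6 h and higher at 24 h, against 15.6. In the same direction 20 were higher at both times, against 19.9, and 5 were lower, against 14.6. Igf1, Hsd11b2, Cd24, Ccl11, Krt8 and Cyp51 were among those lower and then higher, and Sult1a1, a sulfotransferase, Galr2, Gucy1a1, Agtr1a and Igf1r, the receptor of Igf1, among those higher and then lower. Higher at both times were Igfbp5, at 6.05-fold and at least 9.29-fold, Loxl1, at 3.12-fold and 3.73-fold, Ldb3, at 3.02-fold and at least 2.81-fold, and Mxi1 and Gorasp1, each at a log2 difference of 1.58 at 24 h and at 3.45-fold and at least 3.69-fold at 6 h. Dusp1, at 2.37-fold and 3.83-fold, and Lcn2, an iron-binding acute phase protein, at 2.31-fold and at least 2.60-fold, were lower at both times. Probe sets of Mxi1 and Pygb passed the 2-fold rule in both directions, so their values depend on the probe set chosen. Across the 3622 measured genes, which are not independent replicates, the differences at the 2 times had a Pearson r of -0.25 and a Spearman rho of -0.22.

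**Figure D3:**
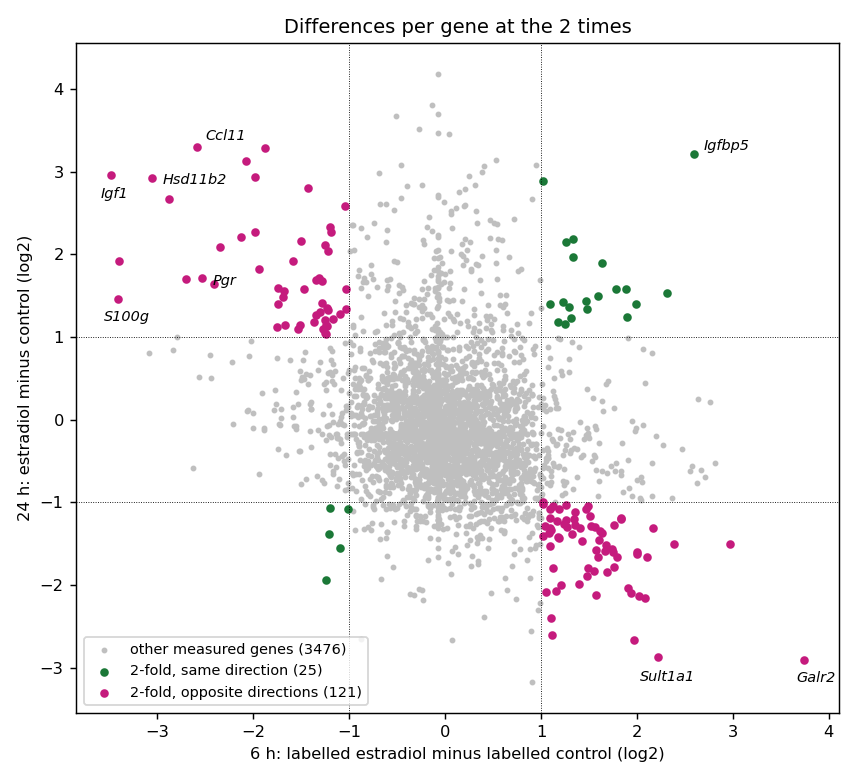
Log2 difference of each of 3622 measured genes at 6 h (horizontal, as labelled) and 24 h (vertical); dotted lines mark 2-fold. The 121 genes past 2-fold in opposite directions lie in the upper left and lower right, and the 25 in the same direction in the other corners.

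A fit of both times together treated them as repeats of the treatment. Its coefficient is the mean of the differences at each time. Its error, with 1 residual degree of freedom, is how far those differences disagree and not replicate noise. Opposite directions therefore cancel in the coefficient and enlarge the error. Among genes past the fold rule at both times, 121 ran in opposite directions and 25 in the same direction. No probe set of 6157 had an adjusted p under 0.05 for estradiol by limma with Benjamini-Hochberg adjustment, and 104 had an unadjusted p under 0.05. With an intensity trend, no filter, quantile normalization or floors at the 20th or 60th percentile, limma also called 0, with 147, 377, 103, 240 and 60 under 0.05 unadjusted. Because opposite directions alone can leave such a fit without calls, it cannot tell whether estradiol changed expression at either time. For time the counts by limma were 0 and 220. Igfbp5 had the lowest unadjusted p, with a log2 coefficient of 2.91 ± 0.37 (SE) and an adjusted p of 0.999 by limma. Its difference at 24 h is a bound with the 24 h control at the floor, so the coefficient and its SE rest on a floor value. A probe set of Igfbp5 was also among those low on the 24 h control alone.

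Per the labels the 2 controls share the vehicle, and they served as background, but they were scanned on different days. Igf1, Pgr, S100g and Hsd11b2 go against the labels at 6 h. This pair may therefore be an estradiol and a control array and no background. More probe sets passed the 2-fold rule between them than in either estradiol comparison, with 519 probe sets higher and 582 lower at 24 h, 17.9% of those above the floor. With arrays scaled to a common median the split was 637 higher against 506 lower, and with quantile normalization 581 against 562. The interferon response list stood apart on the lower side on the 24 h control, with 4 of 14 genes past 2-fold and a median of -0.59 at percentile 0.47. Mx1, an antiviral GTPase, was at least 9.41-fold, Irf7 9.33-fold, Rsad2 6.12-fold and Mx2 5.09-fold lower, and Cxcl10, which interferon induces, 6.35-fold. Control first and then the estradiol label, Mx1 read 949 and 797 at 6 h and 61 and 144 at 24 h, and Cxcl10 773 and 709 at 6 h and 122 and 79 at 24 h. Irf7 read 1285 and 1212 at 6 h, and 138 and 352 at 24 h. Ribosome biogenesis had a median of -1.61, with 8 of 10 genes past 2-fold, Nop58 at 4.52-fold. Medians also stood apart on the lower side for immediate-early genes, at -0.76 with 7 of 22 past 2-fold, and cholesterol synthesis, at -0.48 with 6 of 16. They did so for uterine estrogen response, at -0.51 with 9 of 27 lower and 4 higher, and cytokines, at -0.48 with 9 of 31 lower and 2 higher. Most genes were under 2-fold in translation factors, at -0.31 with 4 of 28 lower and 1 higher, and in skeletal muscle and mesothelium markers, at -0.59 with 2 of 10 lower and 1 higher. Igf1 was 11.8-fold, Ccl2 9.55-fold, Pgr 4.08-fold, Nos2, the inducible nitric oxide synthase, 4.35-fold and Socs3, a brake on cytokine signals, at least 4.26-fold lower. Medians stood apart on the higher side for clock genes, at 0.92 with 4 of 9 higher and 1 lower, and oxidative phosphorylation, at 0.46 with 4 of 54 higher and 1 lower. They also did so for extracellular matrix, at 0.32 with 2 of 32 higher and 1 lower, and for endothelial markers, at 0.46 with 0 of 7 at least 2-fold higher and 1 lower. The genes with the largest differences measured on both sides were Cyb5a, at 5.82-fold, Mpst, at 5.56-fold, Mprip, at 5.48-fold, Speg, at 5.47-fold, and Rrad, at 5.41-fold, higher. Zfp36 was 16.3-fold, Psmd11 13.1-fold, Copz1 11.1-fold and Taf10 9.79-fold lower, of which Psmd11, Copz1 and Taf10 belong to the 38 probe sets low on the 24 h control alone. With quantile normalization Zfp36 was under 2-fold. The brightest probe set of a gene was chosen anew in each setting, so that value may come from another probe set of Zfp36. It is therefore no sign that normalization removed the difference. Esr1 was at least 2.35-fold higher on the 24 h control, and -0.02 on the log2 scale with a floor at the 60th percentile.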

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

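The tests of exchanged labels, of the 24 h differences against the 6 h control, of the limma fit with labels exchanged and of endometrium in a pool were chosen only after the results they bear on were seen. The genes and lists below passed the 2-fold rule, or stood apart from random lists, in opposite directions at the 2 times as labelled. Each value is the log2 difference at 24 h minus that at 6 h, and with 1 array per group this difference was not tested against replicates. The limma fit with the 6 h labels exchanged called 58 probe sets, but its coefficient restates this difference, and its error, with 1 residual degree of freedom, is what the 2 times share and not replicate noise. The difference between the 2 times is a bound, at least this far from 0, where the gene was at the floor on an array. This holds below for B4galt1, Ccl11, Coro1a, Fdft1, Galr2, Idi1, Kcnf1, Krt8, Krt18, Mvd and Oxtr.

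Among estrogen targets and related genes the value was 6.45 for Igf1, 5.98 for Hsd11b2, 5.54 for Cd24, 4.86 for S100g, 4.24 for Pgr, 4.23 for Odc1 and 2.61 for Oxtr, and 1.13 for the uterine estrogen response list. In cholesterol synthesis it was 5.20 for Cyp51, 5.17 for Idi1, 3.67 for Mvd, 3.63 for Fdft1 and 3.51 for Insig1, and 2.36 for the list. In ribosome biogenesis it was 3.77 for Mybbp1a and 2.37 for Ddx21, and 2.07 for the list. The endoplasmic reticulum folding list had 1.16 and the proteasome list 0.76, with Psmc5 at 2.55 and the tRNA synthetase Tars1 at 2.64. Clock genes went the other way, with -3.53 for Dbp, -3.51 for Per2, -3.13 for Nr1d2, -3.04 for Nr1d1 and -1.59 for the list. Genes of contraction and signalling had -4.64 for Gucy1a1, -4.24 for Agtr1a, -3.45 for Pln and 3.14 for Kcnf1. Growth factor and metabolic genes had -6.65 for Galr2, -5.09 for Sult1a1, -3.94 for Cyb5a, -3.72 for Lpl, the lipoprotein lipase, -3.71 for Igf1r, -3.63 for Igfbp3 and -2.40 for Mprip. Immune and surface genes had 5.89 for Ccl11, 4.41 for B4galt1, 3.17 for Nos2, whose probe sets passed the rule in both directions at 24 h, 2.62 for Fcgr2b, 2.37 for Coro1a and -3.47 for Il33. The keratins had 4.43 for Krt18, 4.25 for Krt8 and 3.37 for Krt19.

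Which explanation holds for the opposite directions cannot be told apart. Every test set arrays of different times and scan days against each other, and 17.9% of probe sets differed 2-fold between the 2 controls. If the 6 h labels were exchanged, that pair would itself be estradiol against control, so its 17.9% cannot weigh against an exchange. The smallest SD of the log2 differences, 0.66, lay across scan days, between the array labelled estradiol at 6 h and the 24 h control. The other pair that an exchange would make alike, the array labelled control at 6 h and estradiol at 24 h, had 0.73. That was larger than the 0.70 between the 2 arrays at 6 h. The 6 lists were also picked for opposite directions, which itself pushes such differences to 1 side. Exchanged labels of the 2 arrays at 6 h are a candidate explanation: in 66.7% of the lists, which that selection favours, the array labelled control at 6 h lay apart from the 24 h control on the side of the 24 h estradiol difference, and the array labelled estradiol in 0 of 6. A response at 6 h opposite to that at 24 h, with labels right, would set the array labelled estradiol apart from the 24 h control on the other side, as 33.3% of the 6 lists did; this was set beforehand to count against it, but that bound took the 2 controls to be alike. The interrupted wash of the 24 h control stays open too: without that array 100% of the lists still set estradiol at 24 h apart from the array labelled estradiol at 6 h, which was set beforehand to count against it, but those lists were picked partly on that 6 h array, and against the 6 h control only 33.3% did, cholesterol synthesis at 0.96 and endoplasmic reticulum folding at 0.70. Estrogen exposure of the 6 h control pool with an estradiol pool that had not responded was not tested.

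The keratins Krt8, Krt18 and Krt19, which mark the epithelium lining the uterus, had medians of -1.98 at 6 h and 2.11 at 24 h. The 6 h median is a bound, because Krt8 and Krt18 were at the floor on the array labelled estradiol. The tables exclude none of 3 explanations by tissue carried along. Endometrium in the estradiol pool at 24 h would bring stroma markers up with the keratins, but their median was -0.66. It stood apart in only 1 of 6 settings fixed beforehand, the deposited values that change nothing, with medians from -0.66 to -0.13. The -0.13 equals the log2 ratio of the floors raised to the 60th percentile and is no measured difference. For endometrium in the pool labelled control at 6 h the stroma median was 0.061, inside the random range, with -0.0085 to 0.21 under those settings, where a lower value was needed. Epithelium without stroma stays open too: the 8 other epithelial markers had a median of -0.052 at 24 h and -0.21 at 6 h, which was set beforehand to count against it, but that bound was a poor one because the markers went both ways at 24 h, with Epcam among 2 at least 2-fold higher and 1 at least 2-fold lower. A regulated change of keratins within cells was not tested.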

How the results depend on the processing

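Settings that put another array in place of a control, that exchange labels or that leave out probe sets low on the 24 h control were chosen only after the data were seen. Settings with the mean of both controls or with the 6 h control rest on a label that Igf1, Pgr, S100g and Hsd11b2 go against. Values as deposited were identical, test nothing and are left out of the totals here. No paired analysis was possible because each group had 1 array and the labels carry no replicate numbers, but the limma fit took time, and with it scan day, as a term. Of named genes under planned settings 1149 values kept their direction and side of the rule, 119 lost the 2-fold call, 4 gained one and 6 reversed. Of the 119, 41 were lost with the floor at the 60th percentile, 41 against the mean of both controls and 28 with the mean of a gene's probe sets. A fold given for a gene's brightest probe set therefore need not hold over its other probe sets. Of gene list medians under planned settings 412 kept theirs, 25 lost the call, 24 gained one and 1 reversed. Counts of probe sets stayed within 1.5 times in 30 planned cases and moved further in 36. For the fold rules, the floors and the rule against each of the 2 controls this follows from how they are built. The last of these keeps only probe sets that also pass against the other control, so its counts can only fall. For the other settings the cause was not tested. The 427 higher at 6 h became 719 and 240 with floors at the 20th and 60th percentiles, 1069 and 136 with 1.5-fold and 3-fold rules, and 85 against each of the 2 controls. The 331 lower at 6 h became 774 and 184 by floor, 607 with a pseudocount, 908 and 99 by fold rule, 123 against the mean of both controls, 36 against each, and 170 against the 24 h control. The 511 higher at 24 h became 828 and 290 by floor, 911 and 229 by fold rule, 309 against the mean of both controls, 138 against each, and 325 without the 186 probe sets low on the 24 h control, all of which count as higher by construction. The 515 lower at 24 h became 1045 and 254, 1394 and 121, and 148 against each control. Between the controls the 519 higher became 846 and 270, 1130 and 157, and 170 with the array labelled estradiol at 6 h in place of the 6 h control, and the 582 lower became 1050 and 312, 1210 and 253. The 212 probe sets with opposite directions at the 2 times became 361 and 131 by floor, and the 40 with the same direction 177 and 14, and 96 with a pseudocount. The correlation of the 2 differences across probe sets moved from -0.26 to -0.15 with the floor at the 20th percentile. The limma fit called 0 as labelled under every setting run, with 60 to 377 at an unadjusted p under 0.05, and 58 with the 6 h labels exchanged. Of the lists that stood apart in either setting, some 6 h medians changed sign against the 24 h control. They were those of uterine estrogen response (0.023), translation factors and tRNA synthetases (0.026), oxidative phosphorylation (-0.31), interferon response (0.56) and the circadian clock (-0.057). The 0.023 is the log2 ratio of the 2 floors, so its sign is set by the floors. At 24 h the ribosome biogenesis median became -0.24 against the mean of both controls and -0.76 against the 6 h control, and the interferon response -0.59 against the 6 h control and -0.69 against the array labelled estradiol at 6 h. With the floor at the 60th percentile the 6 h differences of Oxtr and Coro1a became 0.043. The 24 h differences of Gja1, Ccnb1 and Top2a became -0.12, -0.13 and -0.026, and that of Esr1 between the controls -0.016. The values of Oxtr, Coro1a and Ccnb1 are log2 ratios of the raised floors. These genes count among the 6 reversed but have no measured reversal. The floor, between 89.5 and 108 signal units, limits what can be seen of dim genes.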

Other observations

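The test of a defect of part of the 24 h control array was chosen only after the result was seen. Of 11 adipocyte markers 1 was at least 2-fold higher and 2 lower at 24 h, and the list, at percentile 53.7, did not stand apart. Scd, the desaturase that makes monounsaturated fatty acids, was at least 5.01-fold higher with estradiol. Cfd, the serum protease adipsin, was at least 6.28-fold lower and Lpl 6.08-fold lower.

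The 24 h control had 38 probe sets at least 4-fold lower than on each of the other 3 arrays, which lay within 2-fold of each other, out of 3177 that could show this. The other arrays had 9, 1 and 5 such probe sets, for control at 6 h, the array labelled estradiol at 6 h and estradiol at 24 h. Lower expression in that pool is argued against for 7 genes as a set, whose other probe sets were lower there by a median of -0.17 on the log2 scale, that is not lower, with a bootstrap interval from -0.57 to 0.74, but not for each, since that of Padi2 was lower by 1.31 and that of Cebpd by 0.74. A defect of part of the array may account for the pattern, since 76.3% of these probe sets had names starting with rc_AA against 30.2% of those that could show it, and its place on the chip was not tested. Copz1, Dkc1, Psmd11 and Taf10 are among the 38 but not among the 7, so their expression in that pool stays open. Padi2 and Cebpd were named after their values were seen.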
